A study of Homo sapiens with 8 samples.

How the data were processed

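LARP6 eCLIP was analysed in human hepatic stellate cells in 2 conditions, with 2 immunoprecipitated and 2 size-matched input libraries in each, which makes 8 samples. The TGFβ1 groups received 5 ng/ml of TGFβ1, per the labels. The labels of the control samples name them both untreated and DMSO, so whether a vehicle was added is open, and they are called control here. Replicate numbers were taken from the sample titles. The origin of the cells beyond their type was not given in the sources used here.

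The 4 immunoprecipitated libraries each had a peak list, and each condition had 1 further list made by the authors from both of its replicates. Input libraries were not analysed here on their own. Reads were trimmed with cutadapt, aligned with STAR to GRCh38 and handled by molecular identifier with UMI-tools, per the submitters' processing notes, which give no versions and no order. The peak caller, the input normalisation and the rule that joined replicates were not given in the sources used here. The lists have no header. From the range of their values, the deposited log2 column was read as the authors' log2 fold of a cluster over its size-matched input, and the deposited −log10 column as the authors' −log10 p-value of the same comparison, with 400 as its cap. The lists per library hold clusters of all folds. Both reproducible lists hold no peak under 3 in either value. Peaks were called per library, so libraries were compared by overlap of peaks, and the authors' values served to describe, rank and filter peaks within a list. Values of 1 place in several libraries stand side by side without a test. The lists hold no counts, so the depth is unknown, and the number of tested clusters is given in its place.

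A peak was called enriched at a log2 fold of at least 3 and a −log10 p of at least 3. Peaks were counted as shared when they overlapped by at least 1 nt on the same strand. The highest peak of a gene is the one with the higher fold of both reproducible lists, and where several clusters of a library overlapped it, the highest fold was taken. Coordinates are 1-based. Genes came from a RefSeq table of GRCh38.p14 with 59698 genes, which is the build named in the labels. This table gives gene bounds and biotype but no strand, exons or sequence, so the strand of a gene was taken from the majority of clusters that lay in that gene alone. Of 6532 genes with at least 3 such clusters, 99.0% had all of them on 1 strand and 99.7% had at least 80%. A peak was assigned at its midpoint to a small RNA gene first, then to a protein-coding gene, then to another gene, and to the shortest where several remained. The gene of 7 control peaks and 16 TGFβ1 peaks is uncertain, since several protein-coding genes overlap there. Peaks in repeated genes such as tRNA and rRNA may stem from another copy.

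Shares of peaks were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment, against the remaining tested clusters of the condition or against genes with a tested cluster in both libraries. These tests treat peaks or genes as independent. Library values were compared by exact permutation. Wilson intervals at 95% were given for shares. The 23 gene lists held 726 genes, all of which matched the reference, and a further 4 lists were written after the genes with peaks had been seen. For matched random lists, 10000 lists were drawn from 10 classes of tested clusters per gene. The code was checked on simulated data. On the control background of 5377 genes, 124 of 150 planted lists were recovered (82.7%) where members were drawn at a weight of 10, and 2 of 750 tests of unplanted draws were called. On the TGFβ1 background of 5236 genes, 139 of 150 were recovered (92.7%), with 1 of 800. Only lists with at least 10 tested members were used, 15 in control and 16 in TGFβ1, so smaller lists such as the fibrillar collagens were not covered. Adjustment in this check was over these lists, not the 43 tests of the main comparison. The unplanted draws took all genes as equally likely and did not mimic differences in tested clusters per gene. Of 300 planted overlaps, 300 were found. The work was done in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

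The designs, the gene lists, most alternatives and a rule for named genes were set before the data were examined. The rule took LARP6, up to 6 members of each list with a reproducible peak by the highest fold (12 for collagens), the 10 genes with the highest fold in each reproducible list, the 10 highest among peaks of one list that overlap no enriched peak in a library of the other condition, and COL1A1, COL1A2, COL3A1 and ACTA2 in any case. MALAT1 was added after its values were seen. A gene that the rule takes is not reported here. Alternatives were other limits for fold, p and overlap, a reproducible list of own rule, each replicate left out, and the replicate number as a block. Planned comparisons of 5′ untranslated regions and other transcript regions, of distance to the start codon, of folding energy and of 5-mers need exons or sequence and were not run. Distance to the gene's outermost end within 500 nt was used in their place, with this choice made after the data were seen.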

Results

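LARP6 is a La-related RNA-binding protein known for binding a stem-loop at the 5′ end of collagen mRNAs. Its RNA sites were mapped by eCLIP, in which RNA is crosslinked to protein by ultraviolet light, trimmed, immunoprecipitated and sequenced beside a size-matched input. The cells were human hepatic stellate cells, the collagen-producing cells of the liver, either given TGFβ1 at 5 ng/ml, a cytokine that activates them, or not (control, named both untreated and DMSO in the labels). Each condition had 2 immunoprecipitated libraries, and the inputs enter through the fold over input that the authors deposited for each tested cluster. All log2 folds and −log10 p-values per peak below are the authors' values. A peak was called enriched at a log2 fold of at least 3 and a −log10 p of at least 3. The read depth of the libraries is unknown, because the peak lists hold no counts.

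COL1A2, COL1A1 and COL3A1, which encode fibrillar collagen chains, were among the genes with the most LARP6 peaks in both conditions, beside the lncRNA NEAT1 in control. The number of enriched peaks differed between libraries. Control replicates 1 and 2 held 620 and 835 enriched peaks, and TGFβ1 replicates 1 and 2 held 837 and 1985. They lay in 219, 350, 389 and 907 genes. These were 1.21% (95% Wilson interval 1.12 to 1.31), 2.09% (1.96 to 2.24), 2.69% (2.51 to 2.87) and 3.64% (3.49 to 3.80) of 51273, 39880, 31137 and 54536 tested clusters. The intervals cover counting error only. The authors' lists of reproducible peaks, made from both replicates, held 627 peaks in 229 genes for control and 1008 peaks in 395 genes for TGFβ1. Of the control peaks, 547 and 595 overlapped an enriched peak of replicates 1 and 2, and of the TGFβ1 peaks, 900 and 981 did. A listed peak was thus not always enriched in each replicate. Protein-coding genes held 497 control peaks (79.3%) and 933 TGFβ1 peaks (92.6%), a lower share than the 94.0% and 95.7% of the remaining tested clusters (odds ratios 0.246 and 0.556, adjusted p = 7.83e-34 and 1.44e-05, Fisher's exact test). NEAT1 carried much of this in control, and without it the odds ratios were 0.62 and 0.644 (p = 0.00249 and 0.00167, Fisher's exact test). With 2 libraries per condition no exact permutation test can give a two-sided p below 0.333, and nothing in the labels says that replicates came from separate cultures, so the spread between them may be technical.

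**Figure D1:**
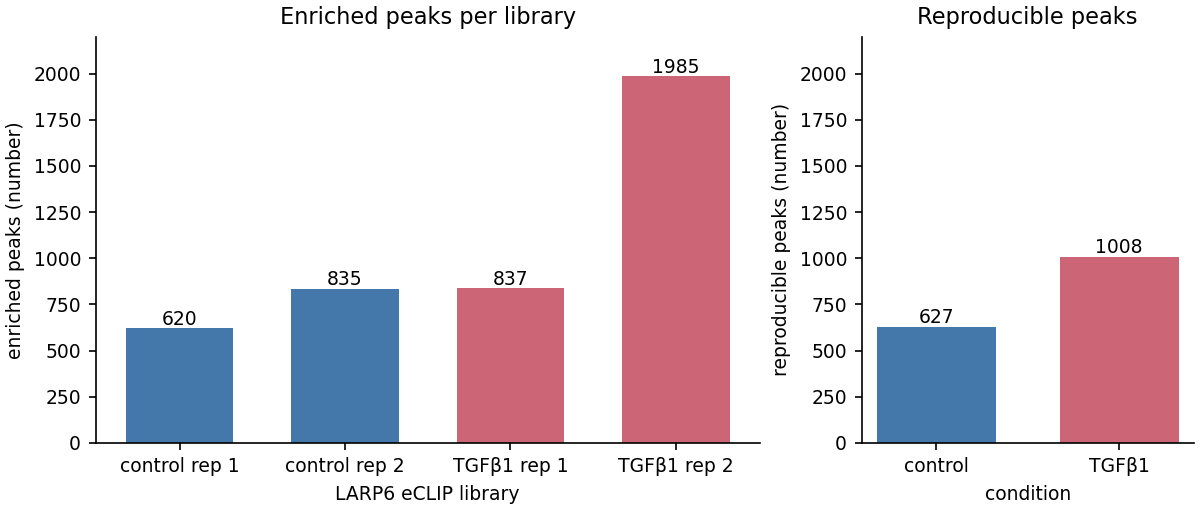
Number of enriched LARP6 peaks in each library (left) and number of peaks in the authors' list of reproducible peaks per condition (right), with control in blue and TGFβ1 in red. Control replicate 2 and TGFβ1 replicate 1 stand at 835 and 837, and TGFβ1 replicate 2 stands at 1985.

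Fibrillar collagen mRNAs carried many reproducible peaks in both conditions. The highest log2 fold of the control list was in COL3A1 (9.17), and that of the TGFβ1 list was in RBFOX2 (9.49), ahead of COL3A1 (9.31). COL3A1, the chain of type III collagen, had 26 reproducible control peaks and 27 TGFβ1 peaks. COL1A2, a chain of type I collagen, had 42 and 53, COL1A1, its partner chain, had 18 and 37, and COL5A1 of type V collagen had 7 in each list. Neighbouring peaks can be parts of 1 site. Merged where at most 20 nt apart, they made 9 and 10 sites in COL3A1, 14 and 17 in COL1A2 and 7 and 9 in COL1A1. COL5A1 had 2 such sites in each list. The highest COL3A1 peak (GRCh38, chromosome 2, 188974466 to 188974471, plus strand, the higher of both lists) lay 95 nt from the annotated 5′ end of the gene. Its log2 fold was 9.21 ± 0.21 in control and 9.31 ± 0.24 in TGFβ1 libraries (SD, n = 2). The highest COL1A2 peak, on chromosome 7, lay 148 nt from the 5′ end, at 7.70 ± 0.60 and 7.88 ± 0.24. The highest COL1A1 peak, on chromosome 17, lay 115 nt from the 5′ end, at 7.81 ± 0.15 and 7.37 ± 0.31. In TGFβ1 replicate 2 a cluster of 7.79 abutted this peak without overlapping it, so the neighbouring 7.15 was taken. The highest COL1A1 clusters had 7.91 and 7.70 in the control libraries and 7.59 and 7.79 in the TGFβ1 libraries. The authors' values of one place are set side by side here without a test.

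Every tested cluster in the first 500 nt of COL1A1, COL1A2 and COL3A1 was enriched in all 4 libraries. Reproducible control peaks there spanned 50201454 to 50201621 in COL1A1 (minus strand), 94394916 to 94395091 in COL1A2 and 188974443 to 188974546 in COL3A1. COL5A1 also had reproducible peaks in this window on chromosome 9, from 134642213 to 134642296 in the control list, with other tested clusters in the window that were not enriched. The window held 5 of 18 control and 7 of 37 TGFβ1 peaks of COL1A1, and 4 of 42 and 3 of 53 of COL1A2. For COL3A1 these were 6 of 26 and 7 of 27, and for COL5A1 5 of 7 and 4 of 7. Most peaks of COL1A1, COL1A2 and COL3A1 thus lay further from the 5′ end. The annotation used here gives gene bounds without exons, untranslated regions or start codons, so the position within the transcript is not given. The mRNA of LARP6 itself carried 3 control and 5 TGFβ1 peaks, which merge to 1 site in each list. All lay within 500 nt of its 5′ end on chromosome 15 (70854050 to 70854158 in the control list). The highest of them had a log2 fold of 5.93 ± 0.22 in control and 5.81 ± 0.56 in TGFβ1 libraries (SD, n = 2). Other named genes with reproducible peaks in this window in both lists were CCNI, NEU1, PCSK1N and PLOD3.

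**Figure D2:**
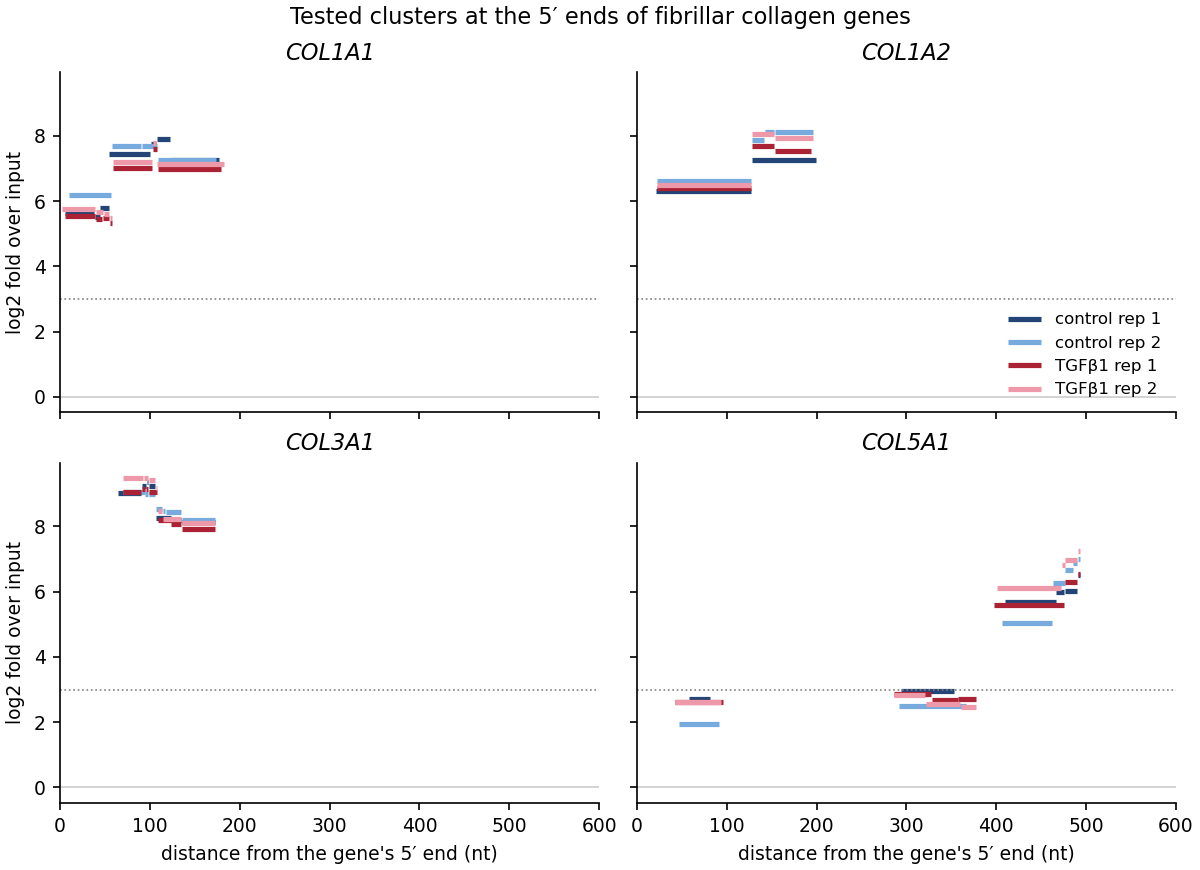
Tested clusters in the first 500 nt of 4 fibrillar collagen genes, drawn from their start to their end as distance from the annotated 5′ end of the gene (nt) against the authors' log2 fold over input, with 1 colour per library. The dotted line marks the limit of 3, and all clusters of COL1A1, COL1A2 and COL3A1 lie above it in all 4 libraries.

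Fixed gene lists were compared with the other protein-coding genes that had a tested cluster in both libraries of the condition. Of 6 fibrillar collagen genes in this background, 4 had a reproducible control peak (odds ratio 50.7, adjusted p = 0.00066, Fisher's exact test with Benjamini-Hochberg adjustment over 43 tests). In TGFβ1 these 4 and COL5A2 made 5 of 6 (odds ratio 66.1, adjusted p = 0.000435, Fisher's exact test). Without TGFβ1 replicate 1 the odds ratio in TGFβ1 was 12.7 (adjusted p = 0.0125, Fisher's exact test). Among other protein-coding genes, 3.80% and 7.04% had a reproducible peak. No other list passed the threshold in either condition. Against random lists matched on the number of tested clusters per gene, the fibrillar collagens no longer passed (permutation test, two-sided, adjusted p = 0.181 in control and 0.258 in TGFβ1).

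Other matrix genes carried peaks without passing the test in the lists from both replicates. Of the other collagens, 3 of 12 in control and 3 of 13 in TGFβ1 had a peak, namely COL6A2, COL6A3 and COL18A1 (adjusted p = 0.139 and 0.369, Fisher's exact test). Of other extracellular matrix proteins, 5 of 39 and 7 of 41 had one, among them FBN1, which encodes fibrillin, and HSPG2, which encodes perlecan. Without control replicate 1 the control test of other extracellular matrix proteins passed (adjusted p = 0.00243, Fisher's exact test). Without TGFβ1 replicate 1 the TGFβ1 tests of other collagens (adjusted p = 0.0134) and of other extracellular matrix proteins (adjusted p = 0.00372) passed by Fisher's exact test. THBS2, which encodes thrombospondin 2, had 8 control peaks and no TGFβ1 peak in the lists from both replicates, and ELN, the elastin gene, had peaks in the TGFβ1 list alone. THBS1 was also in the TGFβ1 list alone, with 2 and 1 enriched peaks in control replicates 1 and 2. The collagen processing list had 2 of 26 and 4 of 26, with LOXL2 and PLOD3 in both lists and BMP1 and P4HA2 in the TGFβ1 list alone. BMP1 and P4HA2 each had an enriched peak in control replicate 2 and none in TGFβ1 replicate 1. PLOD3 had none in control replicate 2 or TGFβ1 replicate 1. Matrix proteases and inhibitors gave 2 of 15 and 3 of 16, with MMP2 and MMP14 in both. MMP14 had no enriched peak in replicate 2 of either condition, and MMP2 had none in control replicate 1. Of TGFβ signalling genes, 2 of 30 and 4 of 33 had a peak, with LTBP1 and LTBP3, which bind latent TGFβ, in both lists and SKI and TGFBR1 in the TGFβ1 list alone.

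Contractile and activation genes gave 2 of 32 in control (TAGLN and S100A11) and 6 of 33 in TGFβ1, with FLNA and FLNC among those in the TGFβ1 list alone (adjusted p = 0.761 and 0.193, Fisher's exact test). ACTN1, an actin crosslinker, was in the TGFβ1 list alone too, with a site log2 fold of 2.85 ± 0.51 in control and 3.50 ± 0.26 in TGFβ1 libraries (SD, n = 2) and an enriched peak in control replicate 2. ACTA2, the smooth muscle actin that marks activated stellate cells, had no enriched peak in any library, with 13, 14, 25 and 27 tested clusters and a highest log2 fold of 1.85. Of AP-1 family genes, 0 of 9 and 2 of 10 had a peak (ATF4 and ATF5). The YAP, TEAD and MRTF list gave 0 of 11 and 1 of 12 (VGLL3).

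None of the lists for translation, secretion and energy metabolism passed the test. Cytosolic ribosomal proteins gave 5 of 65 in control and 4 of 66 in TGFβ1, with RPLP1, RPS19, RPL4 and RACK1 in both lists. RACK1 had no enriched peak in replicate 1 of either condition, and RPL4 had none in TGFβ1 replicate 2. Initiation and elongation factors gave 0 of 36 and 1 of 35 (EIF6). La-related proteins gave 1 of 4 and 1 of 6, in each case LARP6. Endoplasmic reticulum genes gave 2 of 42 and 5 of 51, with SSR1 and TXNDC5 in both lists. Oxidative phosphorylation gave 2 of 40 and 3 of 52, and glycolysis 1 of 14 and 2 of 15. No reproducible peak fell in a gene of the proteasome, the spliceosome and hnRNP proteins, the replication-dependent histones or the mitochondrially encoded list. Of markers of other liver cells, only 1 macrophage gene and 3 cholangiocyte genes in each background and 1 endothelial gene in TGFβ1 were tested, none of them with a peak, and no hepatocyte marker was in the background.

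**Figure D3:**
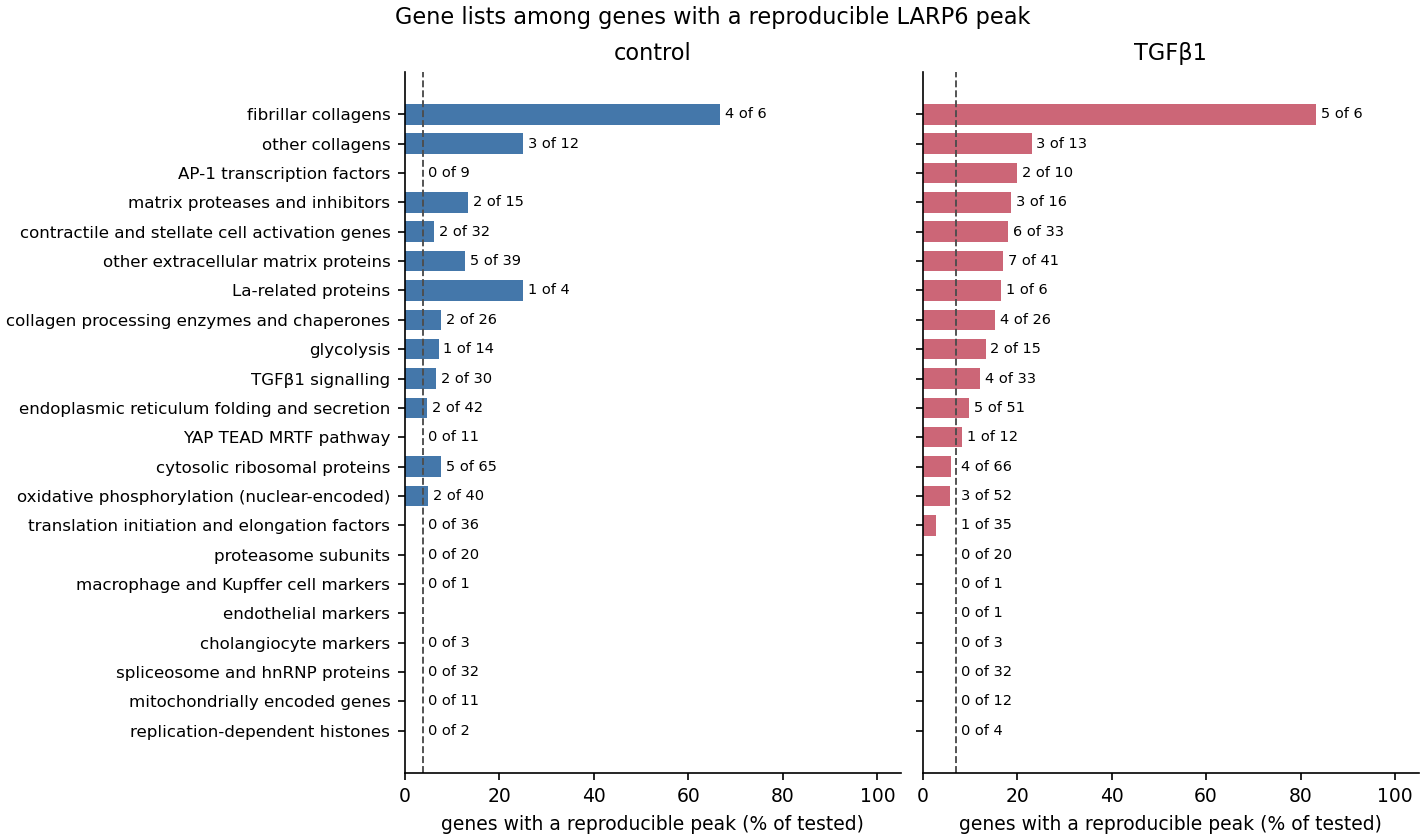
Share of the tested genes of each list (% on the horizontal axis, from 0) that had a reproducible LARP6 peak in control (blue, left) and TGFβ1 (red, right), with the number of genes beside each bar. The dashed line is the share of all tested genes, and fibrillar collagens stand highest with 4 of 6 and 5 of 6.

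Beyond collagens, the genes with the highest peaks were largely shared by both lists. CCNI, a cyclin-like protein gene, had a peak 290 nt from its 5′ end with a log2 fold of 8.59 ± 0.20 in control and 8.39 ± 1.08 in TGFβ1 libraries (SD, n = 2). LRP1, the gene of a large endocytic receptor, had 11 and 16 reproducible peaks, the highest at 8.42 ± 0.99 and 7.70 ± 1.43. The splicing factor gene RBFOX2 had its highest peak 600 nt from the 3′ end of the gene, at 8.06 ± 0.53 and 9.48 ± 0.97. IST1, NEU1 and RDX were also among the 10 highest genes of both lists. CAMK2N1 and COL1A1 were among the 10 highest in control alone, and LTBP1 and PCSK1N in TGFβ1 alone.

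The treatment comparison asks which LARP6 sites differ between control and TGFβ1. Most control sites were also found after TGFβ1. Of 627 control peaks, 499 overlapped a TGFβ1 peak (79.6%, 95% Wilson interval 76.3 to 82.6), and of 1008 TGFβ1 peaks, 615 overlapped a control peak (interval 58.0% to 64.0%). By gene, 196 were in both lists, 33 in the control list alone and 199 in the TGFβ1 list alone. Among 4577 genes tested in all 4 libraries, 19.7 shared genes would arise from independent lists (odds ratio 125, Fisher's exact test, p = 1.6e-194). The test takes all these genes as equally likely to be listed. No null matched on tested clusters per gene was run for it, so its p-value may be far too small. Without TGFβ1 replicate 1, when the peaks of replicate 2 stood for the condition, 34.2% of TGFβ1 peaks were shared.

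Libraries of one condition did not agree more than libraries of different conditions by a testable margin. The mean share of enriched peaks that overlapped was 72.3% between the control libraries and 68.8% between the TGFβ1 libraries, and 51.8% to 72.9% between conditions. The highest of these 6 values was that of control replicate 2 with TGFβ1 replicate 1. The real grouping gave the largest difference within minus between of the 3 possible pairings, for a one-sided exact p of 0.333, the smallest the design allows.

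FLNA, which crosslinks actin, KCNK6, SAMD11, TM7SF3, SEMA7A, DIXDC1, FHL3, XIAP, SYBU and SHISA5 held the 10 highest TGFβ1 peaks that overlapped no enriched peak in a control library. The FLNA peak (chromosome X, 154349962 to 154349980, minus strand) had log2 folds of 4.24 and 7.25 in the TGFβ1 libraries, and the cluster at this place had 1.20 and 2.21 in the control libraries. The KCNK6 peak had 5.04 and 6.45 against 1.38 and 2.58. SHISA5 also had 5 peaks in the control list at other places, and XIAP had 1 enriched peak elsewhere in control replicate 2. The SAMD11 peak (943808 to 943810) abuts another TGFβ1 peak of the gene (943811 to 943881). Control replicate 2 was enriched at the latter, with a log2 fold of 4.22. At the former the control libraries had 3.32 and 3.51, past the fold limit and short of the p limit, so this site was not free of control enrichment. At the TM7SF3 peak they had 3.38 and 2.96, the first of which was also past the fold limit and short of the p limit. Of the 393 peaks in the TGFβ1 list alone, 248 overlapped no enriched peak in either control library, and 245 of these overlapped a tested cluster. With the limit for the log2 fold lowered to 2, 47.3% in place of 63.1% of the 393 had no enriched counterpart.

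AHCY, NEAT1, THBS2, RPL27, BDKRB2, WDR6, LMF1, TWIST2 and the tRNA genes TRY-GTA5-2 and TRR-ACG2-1 held the 10 highest control peaks without an enriched peak in a TGFβ1 library. The AHCY peak (chromosome 20, 34290767 to 34290814, minus strand) had log2 folds of 4.49 and 5.02 in the control libraries and 0.62 and 2.81 in the TGFβ1 libraries. At the THBS2 peak the TGFβ1 libraries had no tested cluster, though 3 clusters elsewhere in the gene were enriched in them. At the BDKRB2 peak TGFβ1 replicate 2 had 3.63, past the fold limit and short of the p limit. Tested clusters numbered 23 and 19 in control and 1 and 1 in TGFβ1 libraries for BDKRB2. They were 47 and 21 against 9 and 6 for LMF1 and 95 and 75 against 9 and 19 for TWIST2. RPL27 held 6 in each library. Whether fewer tested clusters explain the missing enrichment was not tested. Of the 128 peaks in the control list alone, 65 overlapped no enriched peak in either TGFβ1 library, which is 50.8% of them and 16.4% with the fold limit at 2.

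Peaks found in one list alone differed in the kind of RNA. Of control-only peaks, 58 of 128 lay in lncRNAs, all of them in NEAT1, against 8 of 393 TGFβ1-only peaks (Fisher's exact test, TGFβ1 over control odds ratio 0.0251, adjusted p = 9.05e-32). Control-only peaks also lay in tRNA genes more often, with 10 of 128 against 2 of 393 (adjusted p = 4.18e-05, Fisher's exact test). Per library, enriched tRNA peaks numbered 25 and 29 in control and 25 and 17 in TGFβ1. Protein-coding genes held 58 of 128 and 376 of 393 (adjusted p = 3.3e-34, Fisher's exact test), and without NEAT1 58 of 70 (82.9%) and 376 of 393 (95.7%; p = 0.000359, Fisher's exact test). Without NEAT1, lncRNAs held 0 of 70 control-only and 8 of 393 TGFβ1-only peaks (p = 0.613, Fisher's exact test). Neighbouring peaks of a gene are not independent, so these p-values are too small. Between the 192 tested protein-coding genes of the TGFβ1 list alone and the 28 of the control list alone, 0 of 13 gene lists passed the threshold and 0 had an unadjusted p under 0.05 by Fisher's exact test. In 7 of the 13 a single gene was counted, so no p below 0.127 was possible. The other lists could pass only through members in the control list alone. With 192 of the genes in the TGFβ1 list alone, no list could pass by lying wholly there, as the 4 counted contractile and activation genes did. The result therefore does not show that the lists did not differ. Without TGFβ1 replicate 1, 1 list passed, the cytosolic ribosomal proteins (adjusted p = 0.0376, Fisher's exact test).

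NEAT1, the lncRNA that scaffolds nuclear paraspeckles, held 80 of the 627 control peaks and 13 of the 1008 TGFβ1 peaks. Merged where at most 20 nt apart, its peaks made 38 and 12 sites. Of its tested clusters, 126 of 173 (72.8%) and 58 of 141 (41.1%) were enriched in the control libraries and 29 of 95 (30.5%) and 13 of 85 (15.3%) in the TGFβ1 libraries. The means were 57.0% ± 22.4 and 22.9% ± 10.8 (SD, n = 2; exact permutation p = 0.333, two-sided, the smallest possible). MALAT1, another abundant nuclear lncRNA, had 66, 59, 40 and 50 tested clusters and none enriched. Outside NEAT1 the enriched share was 0.967%, 1.96%, 2.60% and 3.62% in the same order of libraries.

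**Figure D4:**
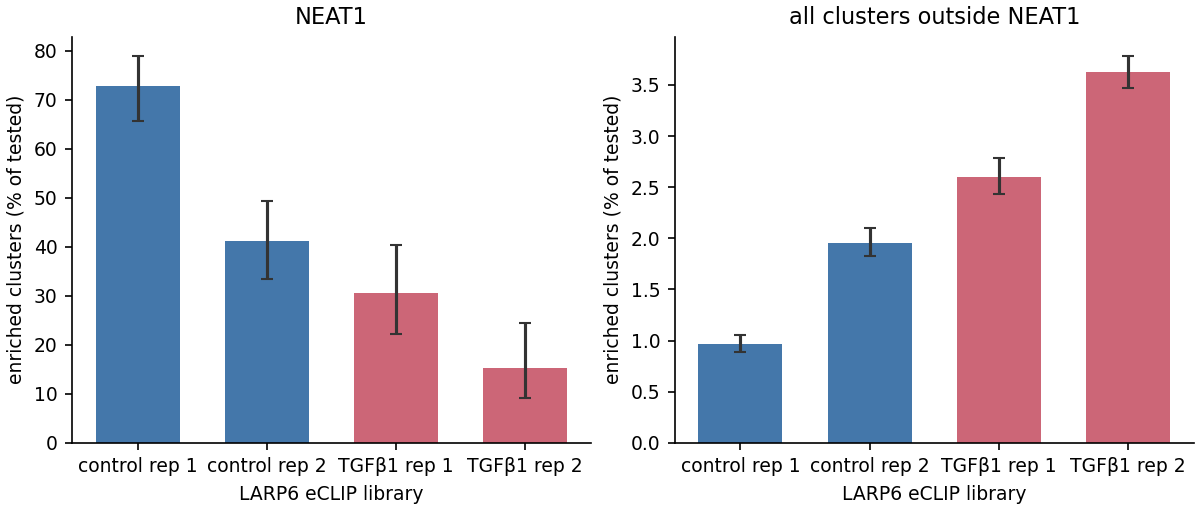
Share of tested clusters that were enriched (% on each vertical axis, from 0; the axes differ in scale) in NEAT1 (left) and in all clusters outside NEAT1 (right) for each library, with 95% Wilson intervals for counting error. NEAT1 lies between 72.8% in control replicate 1 and 15.3% in TGFβ1 replicate 2, and the libraries stand in the opposite order outside NEAT1.

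Position within genes was measured as distance from the outermost annotated end, a measure chosen after the data were seen. In control, 67 of 497 peaks in protein-coding genes (13.5%) lay within 500 nt of the gene's 5′ end, against 8.76% of the remaining tested clusters (odds ratio 1.62, adjusted p = 0.00068, Fisher's exact test). Fibrillar collagens held 20 of the 67, and without them the odds ratio was 1.35 (p = 0.0538, Fisher's exact test). It was 1.01 without control replicate 1. With 1 peak per gene, against the highest cluster of each gene without a peak, it turned to 0.59 (p = 0.0132, Fisher's exact test). The share of peaks was then 11.5%, still above 8.76%, and that of the compared clusters was 18.1%. The turn thus came with the changed comparison set. In TGFβ1, 110 of 933 peaks (11.8%) lay within 500 nt of the 5′ end against 12.2% of the remaining clusters (odds ratio 0.962, adjusted p = 0.763, Fisher's exact test). Without TGFβ1 replicate 1 the odds ratio was 0.843. With 1 peak per gene and the comparison set changed in the same way, it was 0.486 (p = 2.45e-06, Fisher's exact test). The share of peaks was then still 11.8%, against 21.6% of the compared clusters.

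Peaks were more frequent than other clusters near the 3′ end of genes in both conditions. Within 500 nt of it lay 8.45% of control peaks against 4.23% of the remaining clusters (odds ratio 2.09, adjusted p = 0.000114, Fisher's exact test) and 8.57% of TGFβ1 peaks against 5.74% (odds ratio 1.54, adjusted p = 0.00068). Within 200 nt of the 3′ end the TGFβ1 odds ratio was 1.36 (p = 0.131, Fisher's exact test). Per library, the share of enriched peaks near the 5′ end was 14.9% and 10.6% in control and 11.4% and 9.95% in TGFβ1, a difference of −2.08 percentage points (exact permutation p = 0.667, two-sided, n = 2). Control-only and TGFβ1-only peaks near the 5′ end numbered 1 of 58 and 34 of 376 (adjusted p = 0.084, Fisher's exact test).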

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

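The alternatives with merged sites, windows from the gene ends, 1 peak per gene, no fibrillar collagens, no NEAT1, 5′ peaks alone and no ambiguous peaks were chosen after the data were seen, and the cause of a change was not tested unless stated. With 1 peak per gene, the comparison set also changed, to the highest cluster of each gene without a peak. Region, start codon, folding and 5-mer alternatives were not run, for want of exons and sequence. Counts of peaks moved with the limits: at a log2 fold of at least 4, by construction, 371 control and 664 TGFβ1 reproducible peaks were left, and merging peaks at most 20 nt apart left 352 and 555 sites. A fold limit of 2 gave 1258 enriched peaks in TGFβ1 replicate 1. With each TGFβ1 replicate left out, the list held 837 to 1985 peaks. An overlap of 50% of both peaks gave a mean agreement of 54.4% within and 47.4% between conditions, shared shares of 62.7% (control) and 39.2% (TGFβ1), and 61.1% and 71.6% of one-list peaks enriched in no library of the other condition. A fold limit of 2 gave 16.4% and 47.3% for the latter. The shared share of TGFβ1 peaks was 55.0% at a fold of at least 4 and 55.4% by own rule. With each replicate left out, it ranged from 34.2% to 72.3% and that of control peaks from 70.6% to 82.3%.

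The odds ratio for control peaks near the 5′ end ranged from 1.01 to 2.20 with a replicate left out, and was 1.35 with no fibrillar collagens and 0.59 with 1 peak per gene. For TGFβ1 it was 1.03 at a fold of at least 4, 0.838 to 0.843 with a replicate left out, 1.12 within 200 nt, 1.03 within 1000 nt and 0.486 with 1 peak per gene. Near the 3′ end it was 1.36 for TGFβ1 within 200 nt (p = 0.131, Fisher's exact test), and TGFβ1-only over control-only peaks gave 0.636 among peaks enriched in no library of the other condition. The 5′-end difference between conditions ranged from −4.23 to 0.0621 percentage points with a replicate left out. It was −2.08 with the replicate number as a block (exact sign-flip p = 0.5). Same-numbered libraries did not deviate together in enriched peaks per gene (correlation −0.011 across 977 genes). This value cannot exclude a shared culture or day, on which the labels are silent. Lists past the threshold numbered 2 at a fold of at least 4 in control, 1 to 2 (control) and 1 to 3 (TGFβ1) with a replicate left out, and 0 in both against matched random lists. Between conditions they numbered 0 to 1 with a replicate left out. The second list in control was other collagens at a fold of at least 4 (adjusted p = 0.0449, Fisher's exact test). The fibrillar collagen calls held in 5 of 6 alternatives in each condition, all but the matched lists. With 5′ peaks alone all 4 tested members had a peak, so no odds ratio can be given. Of all alternative values of the main results, 75 kept their side or their size, 27 moved, 6 turned direction, 2 gained and 3 lost a call. The gene overlap between conditions passed its test in each alternative run, though none of them matched genes on tested clusters.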

Other observations

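Of the tests on NEAT1, on the length of the lists and on fibrillar collagens, the comparison of equal numbers of top peaks and the matched lists for 5′ peaks were set before their results were seen, though for the latter the counts of collagen genes were already known. The matched lists for peaks anywhere in the gene were planned, but how to read them was set after their result was seen, and the remaining tests were chosen after. tRNA genes held 30 of 627 control peaks (4.78%) and 20 of 1008 TGFβ1 peaks (1.98%), against 0.155% and 0.186% of the remaining tested clusters (odds ratios 32.4 and 10.8, adjusted p = 1.71e-32 and 3.1e-13, Fisher's exact test). The genes were few: 11, 13, 12 and 8 tRNA genes were enriched of 59, 66, 55 and 69 tested in control replicates 1 and 2 and TGFβ1 replicates 1 and 2. The arginine tRNA gene TRR-TCG1-1 had 3 peaks in each list with highest log2 folds of 5.74, 6.88, 5.00 and 4.63. Selenocysteine tRNA TRU-TCA1-1 had 4 and 3 peaks. rRNA genes had 6 and 11 peaks. Other noncoding RNAs had fewer peaks than the remaining clusters, with 0.159% against 1.36% in control and 0.298% against 1.20% in TGFβ1 (odds ratios 0.116 and 0.245, adjusted p = 0.0054 and 0.00582, Fisher's exact test), and RN7SL2, a signal recognition particle RNA, was one of them with 1 and 2 peaks. These genes were named after their values were seen.

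Among 4 gene lists written after the genes with peaks had been seen, so that their p-values are no independent evidence, sterol and fatty acid synthesis had 5 of 26 tested genes with a control peak and 8 of 26 with a TGFβ1 peak (adjusted p = 0.00559 and 0.00246, Fisher's exact test). FASN, FADS2, MSMO1, SC5D and SPRING1 were in both lists. The integrin list had 1 of 7 and 4 of 9 (adjusted p = 0.241 and 0.00559, Fisher's exact test). The 4 in TGFβ1 were ITGA11, ITGAV, ITGB1 and ITGBL1, the last an integrin-like gene and not an integrin subunit. Tetraspanins had 3 of 8 and 3 of 10 (adjusted p = 0.00559 and 0.0394, Fisher's exact test). Lysosomal genes had 4 of 34 and 6 of 29 (adjusted p = 0.0465 and 0.0235, Fisher's exact test). These tests were not repeated with matched random lists.

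NEAT1 had a lower enriched share in both TGFβ1 libraries than in both control libraries. Lower enrichment over the whole library would not give this, since the share outside NEAT1 was 1.65 percentage points higher in TGFβ1 and higher in both of its libraries than in both controls. The p limit alone removed no NEAT1 cluster, since 0 of those in the TGFβ1 libraries passed the fold limit and missed the p limit. In the control libraries too, all NEAT1 clusters past the fold limit (126 and 58) were enriched. A lack of reads could also change the fold or leave places untested, so it is not excluded. NEAT1 had 173 and 141 tested clusters in control and 95 and 85 in TGFβ1. The largest gap between libraries of one condition was 31.7 percentage points, between the controls, close to the difference of −34.1 between the condition means, so a library-to-library difference and the treatment (exact permutation p = 0.333, the smallest possible) cannot be told apart with 2 libraries each.

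The TGFβ1 list of reproducible peaks was longer than the control list. More tested clusters do not account for all of it, since the TGFβ1 libraries held fewer on average (a mean difference of −2740) and TGFβ1 replicate 1 had more enriched peaks than control replicate 1 with fewer clusters, though TGFβ1 replicate 2, with 1985 enriched peaks, also held the most clusters (54536). With the 620 peaks of highest fold in each library, 436 control and 388 TGFβ1 peaks were shared by the replicates, a ratio of 0.89, where all enriched peaks gave 511 and 746, a ratio of 1.46. A candidate explanation is therefore that the longer list follows from more enriched peaks per TGFβ1 library. Whether TGFβ1 or the libraries themselves set that number stays open, with an exact permutation p of 0.333 that the design cannot lower.

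Fibrillar collagen genes had reproducible peaks more often than other genes, and long abundant mRNAs with many tested clusters could also show this. Against lists matched on clusters per gene, 4 genes stood beside 0.699 on average in control and 5 beside 1.71 in TGFβ1 (permutation p = 0.0042 and 0.012, two-sided, adjusted over all lists 0.181 and 0.258). Matching was by class, so it need not be close for genes with very many clusters, such as COL1A2 (146 to 193 per library). The unadjusted values may therefore be too small. For peaks within 500 nt of the 5′ end, all 4 tested genes had one, beside 1.73 and 2.49 in lists matched on clusters near the 5′ end (permutation test, two-sided, adjusted p = 0.0268 and 0.0676). By the reading set in advance, 0.0676 would have counted for the density of clusters as the cause, but every member had a peak, so it is the smallest p these lists allow, and the test was read as undecided after its result was seen. The matched count also includes the enriched clusters themselves, and near the 5′ end every tested cluster of COL1A1, COL1A2 and COL3A1 was enriched. Matching can therefore remove part of the binding, so a list that no longer passes is no evidence for the density of clusters. The density of clusters thus stays open as a part of the cause, and no biological explanation was tested.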
